A study of Homo sapiens with 4 samples.

How the data were processed

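RNA-sequencing profiles of SSP-25 cells were analysed in 4 libraries, 1 transfected with a scrambled control siRNA and 3 with siRNA against JMJD6, numbered 1 to 3 by the labels. RNA was extracted with a commercial kit and libraries were made with a stranded mRNA kit, per the labels, a kind of kit that selects poly(A) RNA. The deposited values are FPKM per gene symbol, 1 table per library, made by the authors. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1 with the genome build hg19. The annotation, filters, read counts and strand setting are not given in the sources used here. Because FPKM are not counts, no count test was run.

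Each table held 26255 symbols with total FPKM of 595930 in the control and 576774, 556072 and 532995 in knockdown replicates 1, 2 and 3. The most abundant entry was MIR5047 in the control (6.99% of the total) and in replicate 1 (5.65%), FTH1 in replicate 2 (1.93%) and FTL in replicate 3 (1.12%). Small RNA genes, which are mostly shorter than a sequenced fragment, held 8.53%, 6.44%, 2.32% and 0.625% of the total. Of the symbols, 25155 matched the reference gene tables, which were used for gene classes and older symbols only. No coordinates were used, since the reference build (GRCh38) differs from that of the files. Between 17056 and 17633 genes were above 0 per library. An exact 0 can be a failed estimate, so genes at 0 are described as listed at 0, with each library's value.

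Absolute depth is unknown. In genes of few fragments the ratio of FPKM between 2 libraries repeats exactly, and the most frequent ratio gave the relative depth of the totals used for normalization as 98.4%, 90.6% and 90.0% of the control in replicates 1, 2 and 3 (337 to 438 genes at the most frequent ratio per pair with the control). No interval from counting error can be given for a value. No pair of libraries shared more than 1 identical value above 0, so each was counted as a separate library.

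Genes with an FPKM of at least 1 in at least 1 library were tested (13183) on log2(FPKM + 1). Log2 differences are on that scale, which understates the change of low genes, while ratios are of FPKM. The test was limma-trend (limma 3.58.1, R 4.3.3), two-sided, 1 control against 3 knockdown libraries, with Benjamini-Hochberg adjustment at 0.05. It has 2 residual degrees of freedom, all from the knockdown libraries, and 4.02 from the prior, and the lone control is assumed to vary like them. An exact permutation of the 4 libraries cannot go below a one-sided p of 0.25 and was not used. A count by size was made beside it: genes at least 2-fold from the control the same way in all 3 knockdown libraries, repeated with each knockdown library as the single reference and in 100 simulations of unchanged groups with the shared control. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

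Gene lists numbered 31, of which 30 had tested members (702 of 847 symbols), and the mitochondrially encoded list had 0 members in the files. For each list, members past the limma test were counted over all genes and adjusted over the list alone. Lists were compared with the other genes by limma's camera with a preset correlation of 0.01 and with an estimated correlation, adjusted over lists, and the list median was ranked among 10000 random lists of the same size matched on expression in 20 bins. The random lists were drawn without regard to correlation between genes. With an estimated correlation camera rests on the residual degrees of freedom, 2 here, so it can call few lists. A call lost there does not show that correlation between genes removed it.

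Named genes followed a fixed rule: JMJD6 and CD274; the 12 highest and 12 lowest genes past the limma test with a mean of at least 5 FPKM in a group and a change of at least 1 in all 3 knockdown libraries, filled up with the genes of the largest smallest-of-3 change where fewer passed; and per list the members that passed, up to 3, or the 1 with the largest change where none did. The rule was applied again without small RNA genes, an addition made after the values were seen. Further list members, H3F3A and the genes named for a single library were also chosen after their values were seen.

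The limma step was tested on simulated data for this comparison over 13183 genes, 200 of them changed. With the spread of all 3 knockdown libraries it recovered 0%, 64%, 100% and 98% of genes changed by 1, 2, 3 and 4 on the log2 scale, with 17 calls among unchanged genes. With the spread of replicates 1 and 2, raised to the median in genes below the median, it recovered 0%, 56%, 88% and 88%, with 11 such calls. Changes of 2-fold were therefore below what the test could call at these simulated spreads.

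To look for siRNA seed matches, 3' UTRs of GENCODE 29 transcripts were searched for all heptamers (7 bases). Of 9030 genes with a mean of at least 5 FPKM, 8564 (94.8%) had a 3' UTR of at least 50 bases, and 14814 heptamers occurred in at least 100 of them. For each heptamer a z compared the log2 differences of genes with and without it, after adjustment for UTR length, GC content and expression. In data simulated from replicate 1, 20 of 20 heptamers whose genes were lowered by 0.2 ranked first. The lowest z over all heptamers in 100 shuffles of that replicate's differences over the genes was -5.27.

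Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, limma without trend and with a robust prior, leaving out each knockdown replicate, a 1.5-fold rule and the estimated correlation in camera. Leaving out small RNA genes, the adjustment over JMJD6 and CD274 alone and alternatives for the correlation between libraries were added after the data were seen. The median log2 difference of all genes stayed between 0.0054 and 0.03 in each setting. Groups, tests, gene lists, the naming rule and these alternatives, except for the additions named here, were fixed before the data were examined. Some genes that the naming rule selects, and 1 gene list, are not reported here. Protein, splicing and chromatin measurements were not analysed here.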

Results

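The data were RNA-sequencing profiles of SSP-25, a cell line established from a human intrahepatic cholangiocarcinoma, a cancer of the bile ducts within the liver. Cells were transfected with a scrambled siRNA (1 control library) or with siRNA against JMJD6 (3 knockdown libraries), and the efficacy of transfection was checked at 48 hours, per the labels. JMJD6 is a Jumonji C domain protein that hydroxylates lysines of splicing factors and has also been described as a histone arginine demethylase. Each library gave an FPKM value (fragments scaled by transcript length and library total) for 26255 gene symbols, of which 13183 reached 1 FPKM in at least 1 library and were tested. The number of fragments per library was not given, and relative depth read from repeating ratios of low values was 98.4%, 90.6% and 90.0% of the control in knockdown replicates 1, 2 and 3. Between 12142 and 12349 genes reached 1 FPKM in each library. The labels do not say whether the knockdown libraries came from separate cultures, so p-values measure only the spread between these libraries, and the lone control was assumed to vary like them. Replicate 3 stood apart from all other libraries, control included, so most genes below are given per library, and the plot of gene lists shows list medians per library.

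The targeted gene was read first, as a check of the labels. JMJD6 stood at 14.5 FPKM in the control and at 2.82, 4.01 and 4.08 FPKM in knockdown replicates 1, 2 and 3, which was 80.6%, 72.4% and 71.9% lower. The knockdown mean was 3.64 ± 0.708 FPKM (SD, n = 3), 4-fold below the control. On the log2(FPKM + 1) scale the difference was -1.76 (SE 0.39), and JMJD6 did not pass the limma test over all genes (adjusted p = 0.9999). Adjusted over JMJD6 and CD274 alone, the 2 genes fixed in advance, the limma p was 0.00791, an adjustment added after the data were seen.

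The series title names PD-L1 as the gene of interest. CD274, which encodes PD-L1, the ligand by which tumor cells restrain T cells through PD-1, was lowest in the control at 0.910 FPKM and stood at 1.86, 2.37 and 4.82 FPKM in the knockdown replicates. These values were 2.05-fold, 2.61-fold and 5.30-fold the control, with a knockdown mean of 3.02 ± 1.58 FPKM (SD, n = 3). The log2 difference of 1.0 (SE 0.51) did not pass the limma test, with an adjusted p of 0.0943 over the 2 fixed genes and 0.9999 over all genes. CD274 was weakly expressed in every library, and in simulated data the limma test recovered 0% of the genes changed by 1 on this scale, so that the missed threshold does not show equal levels.

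Other ligands of immune checkpoints lay on both sides of the control. VTCN1, the checkpoint ligand B7-H4, was the list member furthest from the control, at 54.7 FPKM in the control and 33.4, 17.5 and 6.92 FPKM in the knockdown replicates. LGALS9, encoding galectin-9, was likewise highest in the control at 6.99 FPKM against 5.81, 2.37 and 1.39 FPKM. PVR, the poliovirus receptor and a ligand of TIGIT, was lowest in the control at 13 FPKM against 22.6, 23.0 and 42.3 FPKM, while CD47, the signal that restrains phagocytosis, lay between 12.4 and 14.4 FPKM in all 4 libraries. Of 12 members tested, the control was the lowest library in 3 and the highest in 4, and none passed the limma test over all genes or adjusted over the list alone (smallest adjusted p 0.377). The list's median log2 difference was 0.12 and its mean -0.08, with a limma camera adjusted p of 0.891, and without replicate 3 the median was -0.14.

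Regulators of PD-L1 and genes of the interferon-gamma pathway also lay on both sides of the control. IRF1, which drives CD274 transcription, stood at 11.1 FPKM in the control and 12.4, 7.27 and 11.9 FPKM in the knockdown replicates. STAT2 had the largest difference of the list, 23.6 FPKM against 22.5, 17.2 and 7.62 FPKM. CMTM6, which protects PD-L1 from degradation, was measured at 88.6 FPKM in the control and 67.5, 78.9 and 75.8 FPKM after knockdown. None of the 24 members passed the limma test over all genes or adjusted over the list alone, and the median log2 difference was -0.11 (limma camera adjusted p = 0.571).

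Genes that interferon induces had a negative median difference from the control over the 3 replicates. The median log2 difference of the 34 members was 0.07, -0.33 and -0.46 in replicates 1, 2 and 3, a contrast between replicates that was not tested. Over the 3 it was -0.30, below all 10000 random lists matched on expression, with -0.46 when replicate 1 and -0.15 when replicate 3 was left out. Random lists lack the correlation between list members, estimated at 0.244 here, so this rank can be extreme without an effect of knockdown. IFITM2, a membrane protein that blocks viral entry, stood at 3.16 FPKM in the control and 1.51, 0.614 and 0.516 FPKM after knockdown, and IFIT3 at 14.2 FPKM against 10.4, 6.97 and 4.33 FPKM. OAS2, which makes the activator of RNase L, stood at 3.41 FPKM against 2.79, 0.887 and 0.327 FPKM. ISG15 was highest in replicate 3, at 44.3 FPKM in the control and 58.5, 34.6 and 80.7 FPKM after knockdown. Of the 34 members, the control was the highest library in 11 and the lowest in 2, and it lay between the knockdown replicates in the rest. No member passed the limma test over all genes or adjusted over the list alone. The list passed limma's camera test with a preset correlation (adjusted p = 9.73e-04). It did not pass with an estimated correlation (adjusted p = 0.826), a test with 2 degrees of freedom.

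The machinery of MHC class I antigen presentation had median log2 differences of 0.32, -0.27 and -0.04 in replicates 1, 2 and 3. B2M, the light chain of class I molecules, stood at 1036 FPKM in the control and 1328, 861 and 1275 FPKM in replicates 1, 2 and 3. PSMB10, a subunit of the immunoproteasome, was lower than the control in each replicate, at 52.9 FPKM against 38.6, 25.1 and 17.9 FPKM. None of the 20 members passed the limma test over all genes or adjusted over the list alone. The median log2 difference was 0.04 and the mean -0.10 (limma camera adjusted p = 0.615), and without replicate 1 the median was -0.10 and the list passed with the preset correlation (limma camera adjusted p = 0.0458). With an estimated correlation and all replicates in, its adjusted p was 0.949.

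The next question was which genes differed after knockdown across the transcriptome. Beside JMJD6, among protein-coding and long RNA genes with a mean of at least 5 FPKM in a group, those furthest below the control in all 3 knockdown replicates were MAP1LC3C, H19, KRT13, ALDH3A1 and ANPEP, and those furthest above it were DKK1, CHAC1, TUBB2A and KLHL4. None of these passed the limma test over all genes (each adjusted p 0.9999). The limma test called 1 gene of 13183, MIR658, a microRNA locus at 3206 FPKM in the control and listed at 0 in the 3 knockdown libraries (adjusted p = 6.71e-04). At an unadjusted p under 0.05 the limma test counted 67 genes (0.508%), where about 5% would arise with no effect and a matching spread. Its spread comes from knockdown libraries that include the distant replicate 3, while the control lay near replicates 1 and 2 (Pearson's r 0.970 and 0.971). Replicates 1 and 2 were also further from each other (r 0.962) than from the control, so replicate 3 need not be the only reason for the low count. The lack of calls therefore does not show that genes were unchanged. Without small RNA genes the limma test called 0 genes and counted 64 at an unadjusted p under 0.05. The limma test called 2, 9 and 2 genes when replicates 1, 2 and 3 were left out and 4 with a pseudocount of 5, each time small RNA genes only.

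Among the genes lower after knockdown, H19, an imprinted long non-coding RNA, stood at 145 FPKM in the control and 40.5, 43.6 and 27.7 FPKM in the knockdown replicates (3.91-fold below the control on average). MAP1LC3C, a member of the LC3 family that coats autophagosomes, stood at 8.08 FPKM against 1.29, 1.30 and 0.272 FPKM. ALDH3A1, an aldehyde dehydrogenase, stood at 229 FPKM against 43.6, 81.7 and 19.3 FPKM, KRT13, an epithelial keratin, at 90.3 FPKM against 31.7, 27.3 and 4.82 FPKM, and ANPEP, the cell surface aminopeptidase N, at 69.7 FPKM against 25.7, 19.3 and 8.64 FPKM. ELF3, an epithelial ETS transcription factor, stood at 234 FPKM against 107, 109 and 66.2 FPKM, and VGLL1, a cofactor of TEAD transcription factors, at 71 FPKM against 31.2, 35.6 and 15.4 FPKM. FST, encoding the activin antagonist follistatin, LMO2, a transcriptional adaptor, RTN2, a reticulon of the endoplasmic reticulum, and C9orf84 were lower at levels under 15 FPKM, with control over knockdown ratios of 3.92, 3.12, 2.53 and 2.95.

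Among the genes higher after knockdown, DKK1, a secreted antagonist of Wnt signaling, stood at 32.7 FPKM in the control and 70.3, 83.6 and 116 FPKM in the knockdown replicates, 2.75-fold on average. CHAC1, which degrades glutathione and is a target of the transcription factor ATF4, stood at 2.63 FPKM against 14.5, 6.63 and 7.03 FPKM. TNFRSF12A, the receptor of the cytokine TWEAK, stood at 92.8 FPKM against 273, 199 and 164 FPKM, and PTHLH, the parathyroid hormone-like hormone, at 6.34 FPKM against 23.2, 15.6 and 12.9 FPKM. TUBB2A, a beta-tubulin, stood at 6.60 FPKM against 24.5, 14.7 and 25.5 FPKM and shares sequence with TUBB2B, which makes its value uncertain. IER3, an immediate early gene, ATP1B1, the beta subunit of the sodium pump, and ITGA2, the alpha subunit of a collagen-binding integrin, were 2.13-fold, 1.91-fold and 1.83-fold the control on average. KLHL4, C11orf24 and PHLDA2, an imprinted gene, were 2.56-fold, 1.97-fold and 3.35-fold. Replicate 3 decided much of the PHLDA2 value, at 62.2 FPKM against 19.6 and 17.7 FPKM in replicates 1 and 2 and 9.90 FPKM in the control.

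**Figure D1:**
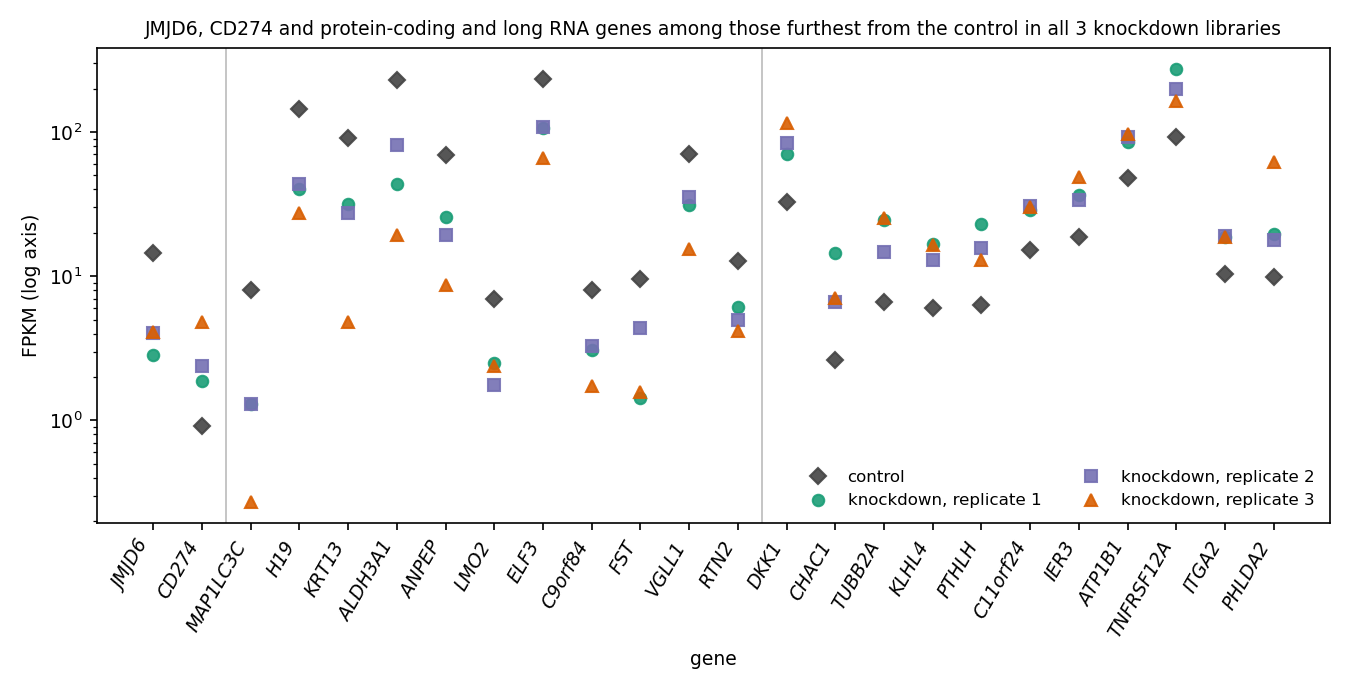
FPKM on a log axis in the control and the 3 knockdown replicates for JMJD6, CD274 and genes other than small RNAs, with a mean of at least 5 FPKM in a group, among those furthest below (middle) or above (right) the control in all 3 replicates, 1 point per library. JMJD6 lies at 14.5 FPKM in the control and at 2.82 to 4.08 FPKM after knockdown, CD274 at 0.910 FPKM and 1.86 to 4.82 FPKM, and of the genes shown the limma test over all genes called none.

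By size alone, 7 genes were at least 2-fold above and 19 at least 2-fold below the control in all 3 knockdown replicates on log2(FPKM + 1), 26 in all, of which 18 were not small RNA genes. Taking a knockdown library as the single reference gave 71 such genes for replicate 1, 38 for replicate 2 and 1201 for replicate 3, of which 54, 26 and 1173 were not small RNA genes. Because the same control enters all 3 differences, some overlap arises with no effect: simulated unchanged groups with the spread of these libraries gave 67.6 genes higher and 67.1 lower on average, and independent lists 0.105 and 0.132. The simulation gave all 4 libraries the same spread, which replicate 3 widens. It was therefore too wide for the control and replicates 1 and 2, and cannot show whether 7 and 19 are few or many. The limma test made 1 call with the control as the single library and 10, 8 and 2141 calls with knockdown replicates 1, 2 and 3 in that place. Without small RNA genes these limma counts were 0, 0, 0 and 2665. The control was the lowest of the 4 libraries in 20.9% of genes and the highest in 19.9%, where chance gives 25% each.

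Small RNA genes took the leading places of the fixed rule. MIR658, SNORA46, SCARNA21, MIR1289-1, SNORA62 and MIR7851 were listed at 0 in all 3 knockdown libraries and at 3206, 21.8, 18.5, 13.7, 8.97 and 7.18 FPKM in the control. SNORA18 and SNORA23, guide RNAs for pseudouridylation, were listed at 0 in the control and at 79.2, 28.7 and 57.7 FPKM and 3.09, 6.72 and 6.77 FPKM after knockdown. Only MIR658 passed the limma test, and its call ended without a filter on low values (limma adjusted p = 0.0895). Of the 88 small RNA genes tested, 68 (77.3%) were listed at 0 in one library and at 5 FPKM or more in another, against 6 of 13095 other genes (0.046%). H3F3A, which encodes histone H3.3, was listed at 0 after knockdown and at 4.19 FPKM in the control, while its near-identical pseudogene H3F3AP4 held 592 FPKM in the control and 585, 530 and 675 FPKM after knockdown, so the value of H3F3A is uncertain.

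Distances between libraries put these differences in scale. FOSL1, a subunit of the AP-1 transcription factor, stood at 194 FPKM in replicate 3 against 14.2, 24.5 and 19.3 FPKM in the control and replicates 1 and 2, and SCD, the stearoyl-CoA desaturase, at 32.3 FPKM against 256, 295 and 241 FPKM. Of the genes tested, 2.10% were at least 2-fold apart between the control and replicate 1, 1.85% between the control and replicate 2 and 3.40% between replicates 1 and 2. Between replicate 3 and the control, replicate 1 and replicate 2 the shares were 18.6%, 17.8% and 15.6%. Pearson's r across genes, which are not independent replicates, was 0.970 and 0.971 between the control and replicates 1 and 2, 0.962 between those replicates and 0.904 to 0.915 for the pairs with replicate 3.

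**Figure D2:**
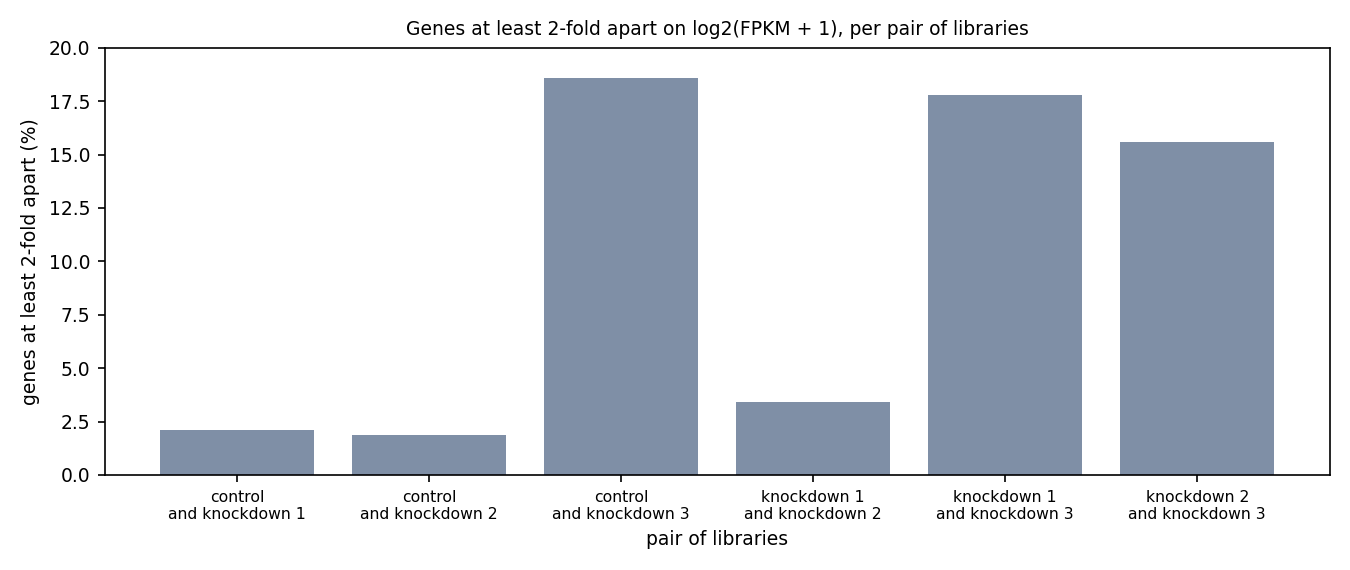
Percent of the 13183 tested genes at least 2-fold apart on log2(FPKM + 1) for each pair of libraries, 1 bar per pair. The 3 pairs with knockdown replicate 3 reach 15.6% to 18.6%, and the other 3 pairs 1.85% to 3.40%.

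Gene groups fixed in advance were compared next. In none of the 30 lists with tested members did a gene pass the limma test, over all genes or adjusted over the list alone, and the smallest adjusted p over a list alone was 0.159, for DKK1 among Notch and Wnt targets. Against the rest of the genes, 9 lists passed limma's camera test with the preset correlation, 6 higher and 3 lower after knockdown. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.826. That version has 2 degrees of freedom and little power. The ATF4 and endothelial lists lost their calls there though their estimated correlations of 0.018 and 0.0141 were near the preset 0.01. For the other called lists the estimate ran from 0.204 (ribosomal) to 0.6 (histones), far above the preset. Their p-values with the preset correlation can therefore be much too small. Without a filter on low values 4 lists passed, and the G1/S, NF-kB, histone, YAP/TAZ and endothelial lists did not (limma camera adjusted p 0.0762 to 0.121). At a filter of 5 FPKM the NF-kB, histone and endothelial lists did not pass (0.0965 to 0.314), and with a pseudocount of 0.1 the endothelial list did not (0.0591). Among 10000 random lists matched on expression, the list median stood at percentile 100, as rounded, for the immediate early, ATF4, NF-kB and histone lists and at percentile 0, 0.01, 0.04, 0.1 and 0.84 for the interferon-stimulated, NRF2, ribosomal, cholesterol and endothelial lists, while the other lists reported here stood between 4.66 and 98.2. Random lists lack the correlation between members of a list, so these percentiles can be extreme without an effect of knockdown. Calls that a list gained when a replicate was left out, given with each list below, rest on the preset correlation.

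Immediate early genes, which cells transcribe within minutes of a stimulus, were the group furthest above the control. Their median log2 difference over 21 members was 0.44, 0.42 and 0.96 in replicates 1, 2 and 3 and 0.49 over the 3, and the control was the lowest library in 13 members and the highest in 0. KLF4 stood at 3.06 FPKM in the control and 6.65, 5.60 and 16.7 FPKM after knockdown, JUN at 11.2 FPKM against 15.5, 19.1 and 23.0 FPKM, and DUSP6, a phosphatase of ERK, at 0.196 FPKM against 0.734, 1.11 and 7.77 FPKM. FOSL1 had the largest difference, mostly from replicate 3. The limma camera adjusted p was 1.54e-07 with the preset correlation and 0.826 with an estimated correlation.

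Genes of the ATF4 and amino acid response had a positive median in each replicate, at 0.28, 0.41 and 0.27 and 0.39 over the 3 for 28 members. SLC3A2, the shared subunit of amino acid transporters, stood at 102 FPKM in the control and 174, 175 and 149 FPKM after knockdown, and STC2, a secreted glycoprotein, at 8.31 FPKM against 25.5, 14.5 and 35.6 FPKM. ATF3, a stress-induced transcription factor, had the largest difference, at 1.65 FPKM against 4.79, 2.11 and 25 FPKM. DDIT4, an inhibitor of mTORC1, was highest in the control at 279 FPKM against 229, 207 and 53 FPKM. The control was the lowest library in 13 members and the highest in 3, with a limma camera adjusted p of 3.73e-04 with the preset correlation and 0.826 with an estimated correlation. The unfolded protein response, a related stress pathway, had a median of 0.08 over 22 members and was not called (limma camera adjusted p = 0.158), with DDIT3 at 14.9 FPKM in the control and 31.2, 18.2 and 71.9 FPKM after knockdown and the chaperone HSPA5 at 196 FPKM against 250, 212 and 235 FPKM.

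Cytosolic ribosomal proteins had a slightly negative median in each knockdown replicate. The median log2 difference of 56 members was -0.10, -0.07 and -0.32 in replicates 1, 2 and 3 and -0.15 over the 3, and the control was the highest library in 28 and the lowest in 1. RPS3 had the largest difference, at 1531 FPKM in the control and 1318, 1491 and 629 FPKM after knockdown, and RPL3 stood at 1510 FPKM against 1090, 1272 and 1059 FPKM. The limma camera adjusted p was 1.92e-04 with the preset correlation, 0.826 with an estimated correlation and 0.869 after quantile normalization, where the median was -0.03. Without replicate 3 the median was -0.09. Ribosomal protein genes have many processed pseudogenes, with which they can share reads.

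Genes of G1/S and DNA replication had a median log2 difference over 38 members of -0.16, 0.84 and 0.27 in replicates 1, 2 and 3. CCND1, encoding cyclin D1, stood at 32.8 FPKM in the control and 36.1, 82.5 and 127 FPKM after knockdown, and PCNA, the sliding clamp of replication, at 67.9 FPKM against 50.1, 159 and 96.5 FPKM. Over the 3 replicates the median was 0.13 (limma camera adjusted p = 0.021 with the preset correlation, 0.826 with an estimated correlation), and without replicate 2 it was -0.12 (adjusted p = 0.648), against 0.43 without replicate 1 and 0.27 without replicate 3. Genes of G2/M and mitosis had a median of -0.04 over 41 members (limma camera adjusted p = 0.873), with the kinase AURKB at 84.6 FPKM in the control and 78.4, 41.5 and 60.4 FPKM after knockdown.

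NF-kB targets and inflammatory cytokines had a median over 23 members of 0.79, -0.14 and 0.23 in replicates 1, 2 and 3. TNFAIP3, a feedback inhibitor of NF-kB, stood at 2.89 FPKM in the control and 11.9, 3.27 and 5.22 FPKM after knockdown, and the adhesion molecule ICAM1 at 13.2 FPKM against 29.3, 9.06 and 16.6 FPKM. CSF1, the macrophage growth factor, had the largest difference and went the other way, at 118 FPKM against 117, 44.1 and 28.8 FPKM. The median over the 3 was 0.31 (limma camera adjusted p = 0.0226 with the preset correlation, 0.826 with an estimated correlation), and without replicate 1 it was -0.0075 (adjusted p = 0.888), against 0.565 without replicate 2.

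YAP/TAZ targets and replication-dependent histones had their largest medians in replicate 3. Among YAP/TAZ targets NT5E, the ecto-enzyme CD73, stood at 2.26 FPKM in the control and 5.31, 3.86 and 21.5 FPKM after knockdown, and CYR61, a matricellular protein, at 83.2 FPKM against 120, 113 and 185 FPKM. The YAP/TAZ median over 24 members was 0.08, 0.07 and 0.68 in the replicates and 0.16 over the 3, and the histone median over 20 members was 0.21, -0.15 and 0.995 and 0.33 over the 3. HIST1H3B had the largest histone difference, at 0.186 FPKM against 0.566, 1.64 and 1.86 FPKM, in libraries selected for poly(A), which most of these mRNAs lack. Limma camera adjusted p values with the preset correlation were 0.021 and 0.0226, with an estimated correlation 0.826 for both lists, and without replicate 3 0.336 and 0.942. The YAP/TAZ median was 0.28, 0.35 and 0.0036 without replicates 1, 2 and 3, and the histone median 0.62 without replicate 2 and 0.0032 without replicate 3. Endothelial markers had a median of -0.53 over 5 members, with the control the highest library in 3 and the lowest in 0. Their limma camera adjusted p was 0.0439 with the preset correlation and 0.826 with an estimated correlation. With the preset correlation it was 0.136 without replicate 3, where the median was -0.14, and 0.0616 without replicate 2. CDH5, the adhesion molecule VE-cadherin, had the largest difference, at 9.11 FPKM in the control and 4.97, 1.89 and 0.299 FPKM after knockdown.

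Apoptosis regulators and hypoxia genes did not pass the camera test with all replicates in. Apoptosis regulators had a median of 0.07 and a mean of -0.02 over 26 members (limma camera adjusted p = 0.873), with the death ligand TNFSF10 at 18.3 FPKM in the control and 10.7, 8.78 and 0.721 FPKM after knockdown. Hypoxia and glycolysis genes had a median of 0.16 over 33 members (limma camera adjusted p = 0.155, 0.826 with an estimated correlation, and 0.00864 without replicate 3), which ran from 0.0858 (without replicate 1) to 0.165 when a replicate was left out, with the vasodilator peptide ADM at 21.6 FPKM against 21.6, 28.1 and 72.2 FPKM.

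Lipid synthesis and antioxidant genes had negative medians over the 3 replicates. Cholesterol and fatty acid synthesis had medians of 0.09, 0.00 and -0.73 in replicates 1, 2 and 3 over 32 members. FASN, the fatty acid synthase, stood at 143 FPKM in the control and 145, 119 and 41.2 FPKM after knockdown. NRF2 and oxidative stress genes had medians of -0.02, 0.07 and -0.62 over 24 members, with the pentose phosphate enzyme PGD at 260 FPKM against 191, 226 and 37.8 FPKM. Both had a limma camera adjusted p of 0.0722 with the preset correlation and 0.826 with an estimated correlation. The preset p was 0.0329 for cholesterol after quantile normalization (median -0.24), and it was 0.00674 for cholesterol and 0.0236 for NRF2 without replicate 1 and 0.0059 and 2.66e-04 without replicate 2. Without replicate 3 the medians were 0.03 and -0.02.

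Groups tied to the known activities of JMJD6 were not called. Splicing factors and SR proteins had a median of 0.17 over 30 members (limma camera adjusted p = 0.0722, 0.826 with an estimated correlation, and 0.0179 without replicate 1), and leaving out 1 replicate moved the median between 0.03 (without replicate 3) and 0.26. U2AF2, a splicing factor that JMJD6 hydroxylates, stood at 72.9 FPKM in the control and 78.9, 69.9 and 79.1 FPKM after knockdown, and PRPF3, a component of the tri-snRNP, had the largest difference, at 19.2 FPKM against 19.1, 24.8 and 81.1 FPKM. Transcription elongation and pause release had a median of 0.15 over 25 members (limma camera adjusted p = 0.288), with MYC at 53.4 FPKM against 55.6, 59.7 and 108 FPKM. Other JmjC-domain demethylases and hydroxylases had a median of 0.03 over 27 members (limma camera adjusted p = 0.891), with C14orf169, a ribosomal oxygenase, at 4.27 FPKM against 4.32, 6.66 and 12.2 FPKM. Without replicate 3 the elongation and JmjC medians were -0.01 and -0.04.

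The simple epithelial keratins KRT7, KRT8 and KRT18 stood at 1761, 1986 and 1504 FPKM in the control and between 1338 and 2422 FPKM after knockdown, while KRT19 stood at 2207 FPKM against 1606, 1802 and 557 FPKM. MUC1, a membrane mucin, had the largest difference among biliary epithelial markers, at 113 FPKM against 99.9, 52.9 and 9.11 FPKM. The biliary list had a median of -0.10 over 17 members (limma camera adjusted p = 0.2, 0.826 with an estimated correlation, and 0.0179 without replicate 2), and its median was -0.03 without replicate 1 and -0.17 without replicate 3. Genes of the epithelial-mesenchymal transition had a median of -0.07 and a mean of 0.05 over 28 members (limma camera adjusted p = 0.615), with the matrix protein THBS1 at 761 FPKM in the control and 451, 368 and 175 FPKM after knockdown. Their median was 4.1e-05 without replicate 2 and 0.14 without replicate 3. Notch and Wnt pathway targets had a median of 0.25 over 13 members (limma camera adjusted p = 0.288), which was -0.18 at a filter of 5 FPKM and 0.06 to 0.19 when a replicate was left out, with the Notch ligand JAG1 at 7.76 FPKM against 17.9, 13.6 and 17.4 FPKM.

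Markers of other cell types were few. Of 27 hepatocyte markers only CYP2E1 was tested, at 0.231 FPKM in the control and 0.736, 0.0727 and 1.03 FPKM after knockdown, and of 20 immune cell markers only CD68, a lysosomal protein not confined to macrophages, at 33.5 FPKM against 44.5, 26.2 and 13.5 FPKM (limma camera adjusted p = 0.542 and 0.571). Stromal fibroblast markers had a median of 0.20 over 7 members (limma camera adjusted p = 0.988), with the matrix protein FBLN1 at 14.4 FPKM against 14, 6.80 and 7.38 FPKM. Without replicate 3 the CD68 difference was 0.03 and the stromal median -0.15. Housekeeping genes had a median of -0.0087 and a mean of 0.02 over 28 members (limma camera adjusted p = 0.891), with the transferrin receptor TFRC at 65.3 FPKM against 97.6, 143 and 115 FPKM. The RNA interference machinery had a median of 0.22 over 13 members (limma camera adjusted p = 0.246), which was 0.03 without replicate 3 and 0.34 without replicate 1, with AGO4, an Argonaute protein, at 6.75 FPKM against 4.94, 4.20 and 1.93 FPKM. Mitochondrially encoded genes had 0 members in the files.

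**Figure D3:**
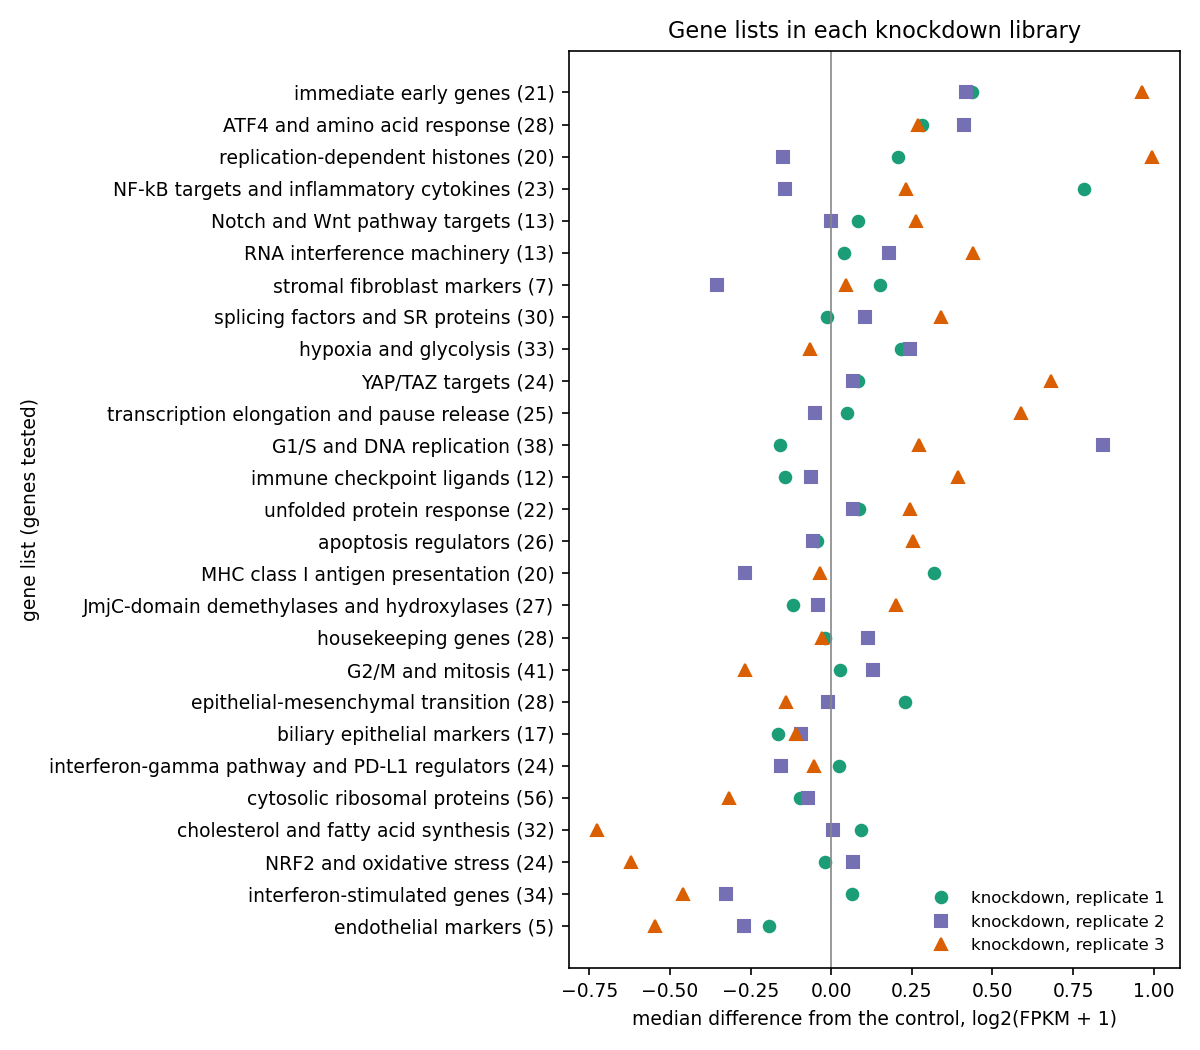
Median difference from the control on log2(FPKM + 1) over the tested members of gene lists with at least 5 of them, 1 point per knockdown replicate, with the number of tested genes in parentheses. Immediate early genes (0.44, 0.42 and 0.96) and the ATF4 and amino acid response (0.28, 0.41 and 0.27) lie above 0 in all 3 replicates, while interferon-stimulated genes lie at 0.07, -0.33 and -0.46.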

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

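The analysis without small RNA genes, the adjustment over JMJD6 and CD274 alone and the alternatives for the mean r among libraries were chosen after the data were seen, and the other alternatives were planned. Of 709 values of named genes under the alternatives, 701 kept their direction and their side of the threshold, and of 389 list medians 341 did. Many named genes were chosen for the same direction in all 3 replicates, so leaving 1 out could not reverse those. Of the named genes only MIR658 had passed as reported, so the same side mostly means not called in either setting. JMJD6 stayed between -1.99 and -1.18 and CD274 between 0.42 and 1.51 on the log2 scale, and CD274 was not tested at a filter of 5 FPKM. The limma test called 1 gene as reported, 4 (all lower) with a pseudocount of 5, 0 without a filter (390 at an unadjusted p under 0.05) and 0 without small RNA genes (64), and 2 to 9 when a replicate was left out (1 to 3 higher and 1 to 6 lower). Genes 2-fold higher numbered 7 as reported, 41 and 1 with pseudocounts of 0.1 and 5, 58 at 1.5-fold and 17 to 34 when a replicate was left out. Genes 2-fold lower numbered 19 as reported, 49 with a pseudocount of 0.1, 110 at 1.5-fold and 24 to 69 when a replicate was left out. Fewer libraries to agree and a lower bar both raise these counts by construction. Lists past camera numbered 9 as reported, 4 without a filter, 0 with the estimated correlation and 7 to 12 when a replicate was left out. The mean r among knockdown libraries was 0.927, 0.962 without a filter and 0.889 at 5 FPKM. Medians of some lists changed sign. At 5 FPKM Notch and Wnt targets stood at -0.179 and stromal markers at -0.0692. When 1 replicate was left out, medians ran from -0.0252 to 0.0701 for housekeeping genes (positive without 1 or 3), -0.101 to 0.12 for MHC class I and -0.00754 to 0.565 for NF-kB targets (negative without 1), -0.121 to 0.433 for G1/S (negative without 2) and -0.2 to 0.138 for epithelial-mesenchymal transition (positive without 2 or 3). Without replicate 3 the sign also changed for cholesterol synthesis (range -0.36 to 0.0339), G2/M (-0.0915 to 0.0849), immune cell markers (-0.797 to 0.0286), their 1 member CD68 (-0.7966 to 0.02864), checkpoint ligands (-0.14 to 0.245), JmjC proteins (-0.0356 to 0.0967), stromal markers (-0.145 to 0.245) and elongation (-0.0105 to 0.301). Lists that kept their sign moved by over 1.5 times for apoptosis (0.00843 to 0.177), interferon-gamma (-0.186 to -0.0349), the unfolded protein response (0.0842 to 0.145) and hepatocyte markers (0.149 to 0.607). The cause was not tested for these. No paired analysis was possible because the single control carries no replicate number. Unknown depth leaves the counting error of low genes such as CD274 unmeasured.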

Other observations

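Tests chosen only after the result was seen were the comparison of seed heptamers between libraries, the JMJD6 level in replicate 3 and both tests on small RNA genes. Each knockdown library had genes of its own, and those named here were chosen, after their values were seen, from the 10 furthest above and the 10 furthest below every other library, among genes averaging at least 5 FPKM and with small RNA genes left out. In replicate 3, SNAPC1, a subunit of the snRNA-activating complex, stood at 164 FPKM against 12.9, 11 and 13.4 FPKM in the control and replicates 1 and 2, and PGF, the placental growth factor, at 23.7 FPKM against 2.28, 3.22 and 2.77 FPKM. The long non-coding RNA NEAT1, the scaffold of paraspeckles, was lowest there at 17.9 FPKM against 234, 325 and 165 FPKM, as were the water channel AQP3 (1.03 FPKM against 20.4, 34.9 and 21.7 FPKM) and SCNN1A, a subunit of the epithelial sodium channel (4.10 FPKM against 53.2, 48.9 and 46.9 FPKM).

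In replicate 2 the genes furthest above the other libraries included CDCA7 (16.0 FPKM against 4.63, 2.93 and 4.17 FPKM in the control and replicates 1 and 3) and the replicative helicase subunit MCM6 (35.2 FPKM against 14.7, 7.05 and 14.1 FPKM). IRAK1, a kinase of interleukin-1 receptor signaling, was lowest there at 62.4 FPKM against 156, 189 and 142 FPKM. In replicate 1 the keratin KRT81 stood at 36.2 FPKM against 6.43, 6.79 and 3.36 FPKM in the control and replicates 2 and 3. SDC4, the heparan sulfate proteoglycan syndecan-4, was lowest in replicate 1 at 13.3 FPKM against 107, 94.1 and 198 FPKM, as was LBR, the lamin B receptor, at 9.95 FPKM against 32.7, 47.6 and 32.2 FPKM.

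Over all searched genes, a different 3' UTR heptamer went with the lowest values in each knockdown library: GAGATGA in replicate 1 (z -12.33 there, 0.88 and 0.51 in replicates 2 and 3), TTGAAGC in replicate 2 (z -9.26, 0.04 and 0.88 in replicates 1 and 3) and CTACTCT in replicate 3 (z -7.61, -0.87 and -0.79 in replicates 1 and 2). Base composition is argued against as the whole cause, since the lowest z of other heptamers made of the same bases was -3.61, though the pyrimidine-rich CCTCTCT and CTTCTCT at -5.55 and -5.24 in replicate 3 leave a part of it open there. Of the searched genes at least 2-fold lower than in every other library, 21 of 26 (80.8%) in replicate 1 held one of its 3 leading heptamers against 29.2% of all searched genes, but only 2 of 9 (22.2%) in replicate 2 held one of its own against 26.0%, and the heptamers were chosen on these data. A candidate explanation is that the 3 libraries received siRNAs with different seeds. The least negative leading z was -7.61, below the -5.27 reached with shuffled genes. The shuffles used the differences of replicate 1 alone and break any link between 3' UTR sequence and expression. CCTCTCT, at -5.55, also passed that bound in replicate 3. However, CTACTCT occurs in none of the 4 JMJD6 transcripts searched, unlike GAGATGA, TTGAAGC and GCTACTC, the next heptamer of replicate 3 (29.4% of all heptamers occur there). The labels do not say how many siRNA sequences were used, and no biological explanation was tested.

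Replicate 3 differed from each other library in 1201 genes at 2-fold, against 26 for the control and 71 and 38 for replicates 1 and 2, a structure of the samples other than control against knockdown. Stronger knockdown of JMJD6 mRNA is argued against, as it stood at 4.08 FPKM in replicate 3, near the 4.01 FPKM of replicate 2 and above the 2.82 FPKM of replicate 1. JMJD6 protein was not analysed, so a stronger loss of protein stays open. Matches to its 3 leading heptamers did not account for most of the searched genes lower in it. Of these, 127 of 479 (26.5%, exact 95% interval 22.6 to 30.7) held one, against 18.8% of all searched genes. The rest of the 657 lower genes were not searched, and shorter matches or matches outside 3' UTRs were not counted. A trend on transcript length and GC content is argued against too, since 101.5% as many genes (1091 against 1075) were at least 2-fold apart after its removal, among the 90.5% of genes with values. A different culture, harvest or library batch stays open, as the labels name none, and a seed-independent effect of its siRNA was not tested.

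Small RNA genes led the changed genes, MIR658 among them. Calls also arose with a knockdown library in the control's place. The limma test called 8 genes with replicate 2 as the single library against 1 with the control. As given above, none of these calls remained when small RNA genes were left out and the test was fitted again, though the class of each called gene was not listed. Such counts depend on the spread of the other libraries and cannot decide whether MIR658 responded to loss of JMJD6. Values resting on few fragments in genes shorter than a fragment may account for calls of small RNA genes: the share listed at 0 in one library and at 5 FPKM or more in another was 1686 times as high in small RNA genes as in other genes. The share largely restates the swings by which these genes were noticed, and it measured neither fragment number nor gene length.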
